A study of Rattus norvegicus with 841 samples.

How the data were processed

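The series measured RNA in rat blood by sequencing, in libraries made from polyadenylated RNA after Trizol extraction. It holds 841 libraries from 84 rats, in 4 sets: untreated rats bled daily, 8-week-old male rats given saline, carbon tetrachloride (CCl4), isoniazid or valproate at several doses, 6-week-old rats, and rats of 3 ages given valproate. The deposited values are counts: each of the authors' files lists the read counts of one library by transcript, with the gene name beside each transcript. The authors' processing notes name HISAT2 and the rat assembly mRatBN7.2. The counting tool and the versions are not given in the sources used here. A median of 73.9% of the counts of at most 10 were even in a library, which would follow if both reads of a pair were counted, so counts are treated as reads and not as molecules.

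Counts of the 82183 transcripts were summed to 24897 gene names. The files held 0 transcripts without a gene name and 0 genes with a mitochondrial name. Of the gene names, 22127 were found as symbols in a table of the rat assembly GRCr8 and 128 as synonyms, and 2642 were in neither. That table has positions on an assembly other than mRatBN7.2, so genes are given by the name in the files and no positions are printed.

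Total counts per library ran from 17.5 to 245 M (mega counts), with a median of 31.7 M. A set of 13 globin genes took a median of 82.2% of the counts in untreated whole blood, 84.4% in the dose set, 85.3% in the 6-week set, 77.5% in the age set, 84.6% in the red blood cell fraction and 2.42% in peripheral blood mononuclear cells (PBMC). The counts outside globin had medians of 5.50, 4.68, 4.60, 7.01, 4.76 and 24.4 M in the same order. Confidence intervals of a share are 95% Wilson intervals, and the limit that a count of 0 allows is 3 counts per library. Both cover counting error only, since amplified copies are not independent molecules.

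The design, the comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where an alternative is said to have been chosen later. Groups follow the treatment labels in the untreated, dose and age sets. In the 6-week set the treatment labels contradict the codes in the library titles in drug, dose and day, so its 240 libraries were grouped by the 8 title codes and no drug is named. The 7 libraries titled GC4 but labelled valproate 1000 mg/kg on Days 4 to 10 were placed in no group. The series design gives a dose on Day 3 or Day 8 without saying which set had which, and the labels differ on an intravenous or intraperitoneal route.

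Each of the 19 comparisons was fitted with edgeR 4.0.16 (TMM factors, filterByExpr with a minimum count of 10, quasi-likelihood F test), with p adjusted by Benjamini-Hochberg over the genes tested and a threshold of 0.05. Comparisons of days in untreated rats and of blood fractions had sex as a covariate. The mean over dose groups was set against saline within 1 day. The test between sexes used counts summed per rat, and the test among title codes used counts summed per code and number. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Levels are CPM (counts scaled to library size by edgeR) with TMM factors, given as mean ± SD.

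A total of 25 gene lists, for blood cell types, liver and responses, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation, for lists with at least 5 tested members. The lists were erythroid, heme synthesis, mature neutrophil, neutrophil granule, monocyte, B cell, plasma cell, T cell, NK and cytotoxic, platelet, eosinophil and basophil, MHC class II, hepatocyte, interferon response, inflammatory cytokine and NF-kB, immediate early, glucocorticoid, oxidative stress, p53, proliferation, heat shock and unfolded protein, integrated stress response, fatty acid oxidation and PPAR, sex-linked, and mitochondrial genes. The mitochondrial list had 0 genes in the files and gave no test. Members that passed were counted over all genes tested and again adjusted over the list alone. A list score is the mean log2 CPM of a list's genes in a library, with TMM factors over the whole set and globin counts kept in the library size.

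Named genes were up to 4 members with the smallest p among those that passed, from each list whose camera test passed or that had at least 3 members past the threshold, and the 5 largest rises and 5 largest falls among genes that passed with a mean of at least 10 CPM and a symbol that is not only an identifier. Hbb, Alb, S100a8, Cd79a, Cd3e, Pf4 and Xist could be given anywhere as level checks. Some genes that this rule takes in are not reported here.

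The alternatives were DESeq2 1.42.0, other size factors within edgeR, no filter on low counts, removal of globin genes, removal of globin and erythroid genes, a block for the rat or replicate number, a difference in differences from Day 2, other reference days, and leaving out each rat in turn. Added after seeing the data were other pairs of days (Day 9 against 4, Day 21 against 11, Day 5 against 3, Day 9 against 6, Day 10 against 7, and Day 3 in place of Day 2), removal of hepatocyte genes, sex without Day 1 and the 6-week set without its last date and undated libraries. Each comparison was also refitted on up to 100 other splits of its samples. Fits were tested on simulated data with 200 genes changed in each comparison. Libraries of different rats of the same group and day or date were checked for duplicates on genes with at least 50 counts and none was found. Pairs across groups or days were not checked. Xist, transcribed from the inactive X chromosome of females, fitted the labelled sex in every untreated library. R 4.3.3, data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used. A permutation test used 100000 resamples.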

Results

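Blood RNA was sequenced in 841 libraries from rats bled every day. The untreated set followed 3 male and 3 female rats of 8 weeks over Days 1 to 21, with 126 whole blood libraries and, on Day 21, 6 red blood cell and 6 PBMC libraries. The dose set held 264 libraries of 8-week male rats given 0.9% saline, CCl4 at 4 doses between 0.5 and 2 ml/kg, isoniazid at 4 doses between 400 and 3200 mg/kg, or valproate at 4 doses between 250 and 2000 mg/kg, with 3 rats per arm at the start. CCl4 is a solvent that injures the liver, isoniazid is an antituberculosis drug and valproate is an antiepileptic, both with liver toxicity. The age set held 199 libraries of male rats labelled valproate 500 mg/kg, over Days 1 to 14 and with no saline rats. It had 5 rats each of 3 to 4 weeks, 8 weeks and 8 to 9 months. The 6-week set held 240 libraries of male rats. Total counts ran from 17.5 to 245 M (mega counts) in untreated whole blood, 20.3 to 28.7 M in PBMC, 21.6 to 37.0 M in the red blood cell fraction, 19.8 to 62.5 M in the dose set, 20.1 to 90.0 M in the 6-week set and 18.2 to 45.1 M in the age set. In the lists below, 128 camera calls were made over 18 comparisons at the preset correlation and 1 held with an estimated correlation, that of the hepatocyte list on Day 4 against Day 2 of the age set.

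The first comparison followed untreated rats over days of daily bleeding, with no unbled rats beside them. In these rats, erythroid genes were higher on Day 9 than on Day 2 and some genes of several white cell types were lower. Of 31 erythroid genes, 23 rose (28 adjusted over the list alone), with a median log2 fold change of 1.43. Rhag, a membrane protein of the Rh complex of red cells, went from 3.57 ± 1.64 to 11.7 ± 2.36 CPM (log2 fold change 1.73, SE 0.25, 6 rats per day). Of 12 genes of heme synthesis, 6 rose (11 over the list alone). Of 13 proliferation genes, 5 rose and 1 fell (7 and 1 over the list alone), and Mki67, made in dividing cells, went from 9.84 ± 6.41 to 69.8 ± 16.9 CPM (2.87, SE 0.42), while Pcna was lower at -0.71. The adjusted p with an estimated correlation was 0.211 for each of these 3 lists.

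Some genes of monocytes, neutrophils, T cells and NK cells were lower on Day 9, while most members of these lists did not pass. Of 12 monocyte genes, 4 fell (6 over the list alone, adjusted p = 0.286 with an estimated correlation), among them the lysosomal Cd68 at -1.54 (SE 0.24) and the receptor Csf1r at -1.11 (SE 0.30). Of 14 mature neutrophil genes, 4 fell (5 over the list alone), and Csf3r, the receptor for granulocyte colony-stimulating factor, stood at -0.77 (SE 0.24). Of 9 neutrophil granule genes 3 fell (5), of 13 inflammatory cytokine and NF-kB genes 3 (4), of 9 immediate early genes 4 (5) and of 11 heat shock genes 4 (8), with an adjusted p = 0.211 with an estimated correlation in each. Of 18 T cell genes 2 fell (4 over the list alone, adjusted p = 0.717 with an estimated correlation), and of 12 NK and cytotoxic genes 2 fell (adjusted p = 0.382 with an estimated correlation), while 6 were lower and 1 higher over the list alone. B cell, plasma cell and MHC class II genes had 0 of 14, 7 and 9 past the threshold. Ribosomal RNA moved with these lists, and Rn18s, which selection for polyadenylated RNA should deplete, went from a mean of 196.6 to 773.9 CPM (1.99, SE 0.50). edgeR called 1369 of 11016 genes, 812 up and 557 down, and 2265 with a block for the rat. Day 9 against Day 4, a pair chosen after seeing the data, gave 24 genes, and the count was 214 without female rat 3, 222 without female rat 1, 608 without male rat 3, 890 without male rat 2 and 2182 without male rat 1.

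**Figure D1:**
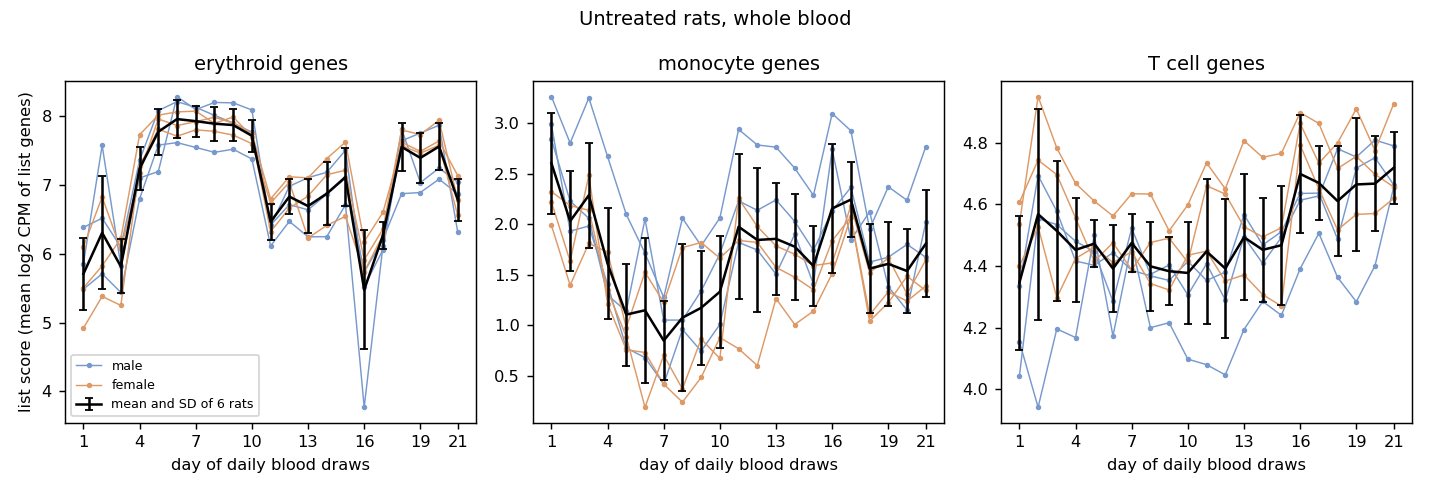
List scores (mean log2 CPM of the list's genes) of erythroid, monocyte and T cell genes by day in the 6 untreated rats, with thin lines for single rats and black for the mean with SD. The mean erythroid score was 5.82 on Day 3, 7.24 on Day 4, 7.72 on Day 10, 6.47 on Day 11, 5.48 on Day 16 and 7.56 on Day 18.

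Between Day 10 and Day 21 the direction was the opposite. Among 31 erythroid genes, 22 fell (24 over the list alone, median -0.94), and Slc4a1, the band 3 anion exchanger, went from 1245 ± 459 to 397 ± 140 CPM (-1.64, SE 0.25). Of 12 heme genes, 5 fell (7 over the list alone), Fech, which puts iron into heme, at -1.30. Of 14 mature neutrophil genes, 8 rose (10 over the list alone), and S100a9, a subunit of calprotectin, went from 59.9 ± 24.2 to 121 ± 37.2 CPM (1.08, SE 0.22). Of 18 T cell genes, 12 rose and 1 fell (the same counts over the list alone), and Cd3e, a chain of the T cell receptor complex, went from 26.5 ± 3.57 to 45.0 ± 6.22 CPM (0.76, SE 0.14). The adjusted p with an estimated correlation was 0.462 for each of these lists. Of 9 MHC class II genes 7 rose and of 12 monocyte genes 3 rose (5 over the list alone), both with an adjusted p = 0.546 with an estimated correlation. Of 17 platelet genes 6 fell, Itgb3, a chain of the fibrinogen receptor, at -1.67. Of 12 inflammatory genes 4 rose, of 8 sex-linked genes 4 fell (5 over the list alone), both with an adjusted p = 0.462 with an estimated correlation, and Xist stood at -1.59. edgeR called 2662 of 10833 genes, 1201 up and 1461 down. Without male rat 3 the count was 1737. Day 21 against Day 11, chosen after seeing the data, gave 3999 genes, and there Fech and Alas2 were higher instead, at 0.28 and 0.64.

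Neighbouring days differed in steps, picked with their named genes after the counts of all days were seen. Day 2 against Day 1, across a change in the run of library numbers, gave 2999 genes, 1272 up and 1727 down. Day 4 against Day 3 gave 1506 genes, with 29 of 31 erythroid genes up, Gata1, the erythroid transcription factor, at 1.57 (SE 0.18). Day 11 against Day 10 gave 1764 genes with 30 of the 31 down. Day 16 against Day 15 gave 2786 genes, with 27 erythroid and 8 of 17 platelet genes down, 8 T cell genes up and 2 down, and Day 18 against Day 17 gave 1481 genes with 28 erythroid genes up. Each step compares 6 rats with themselves, fitted without a block.

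Female and male rats, compared on counts summed over all days (3 against 3), differed in sex-linked genes. Xist stood at 95.5 ± 4.67 CPM in females and 0.315 ± 0.0159 in males, a log2 fold change of 8.24 (SE 0.11), and the Y-linked Kdm5d at -10.45 and Uty at -9.15. Of 8 sex-linked genes 2 were higher and 3 lower in females (4 and 3 over the list alone), including Kdm6a, which escapes X inactivation, at 0.59 (SE 0.06). Among 22 interferon response genes, 0 passed over all genes with edgeR and 14 were lower in females over the list alone, with a median of -0.73 and an adjusted p = 0.629 with an estimated correlation. Isg15, a ubiquitin-like modifier induced by interferon, stood at -1.50 (SE 0.24). Of 13 monocyte genes, 8 were lower in females over the list alone (median -0.68, adjusted p = 0.673 with an estimated correlation). edgeR called 10 of 16378 genes, 3 higher and 7 lower in females, with 1529 at an unadjusted p under 0.05. DESeq2 called 259, but on simulated data with this design 32.5% of its calls were false.

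The red blood cell fraction and PBMC of Day 21 differed widely. In extra tests against whole blood of Day 21, edgeR called 2 of 10730 genes for the red blood cell fraction, with 1292 at an unadjusted p under 0.05. For PBMC it called 5256 of 13215. The differences below therefore do not isolate red cells from whole blood. The red blood cell fraction had 28 of 31 erythroid genes higher than PBMC and 2 lower (median 6.01), and 11 of 12 heme genes higher (median 4.75). Car2, the carbonic anhydrase of red cells, stood at 2994 ± 411 against a mean of 21.3 CPM (7.18, SE 0.34, 6 libraries per fraction). Neutrophil genes were also in this fraction. Of 15 mature neutrophil genes 10 were higher (11 over the list alone), S100a9 at 313 ± 115 against 5.04 ± 1.43 CPM (5.94, SE 0.25), and of 8 granule genes 7 were higher, the collagenase Mmp8 by 5.71. The adjusted p with an estimated correlation was 0.154 for these 4 lists.

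PBMC held more platelet and early response RNA. Of 17 platelet genes 16 were lower in the red blood cell fraction, Pf4, a chemokine of platelet granules, at 442 against 1123 CPM (-1.34, adjusted p = 0.392 for the list with an estimated correlation). Of 13 immediate early genes 9 were lower (10 over the list alone), Jun at 7.90 against 72.2 CPM (-3.21, SE 0.17, adjusted p = 0.154 for the list with an estimated correlation). Among 18 T cell genes 4 were higher in the red blood cell fraction and 1 lower, with Cd3e at 145 against 111 CPM. TMM factors scale the fractions to each other, and globin took a median of 84.6% of counts in the red blood cell fraction and 2.42% in PBMC. These levels are thus not shares of all RNA, and do not show that the red blood cell fraction held more T cell RNA than PBMC. Of 22 interferon genes 8 were higher and 1 lower, of 16 proliferation genes 7 and 1, of 13 oxidative stress genes 7 were higher and of 15 fatty acid oxidation genes 5. Their adjusted p with an estimated correlation was 0.392, 0.217, 0.278 and 0.217. Of 8 eosinophil and basophil genes 4 were higher (adjusted p = 0.154 with an estimated correlation), among them Alox15, which red cell precursors also make, by 7.53. NK and plasma cell genes had 0 of 12 and 0 of 9 past the threshold. edgeR called 3572 of 13192 genes, 1928 higher in the red blood cell fraction and 1644 higher in PBMC.

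**Figure D2:**
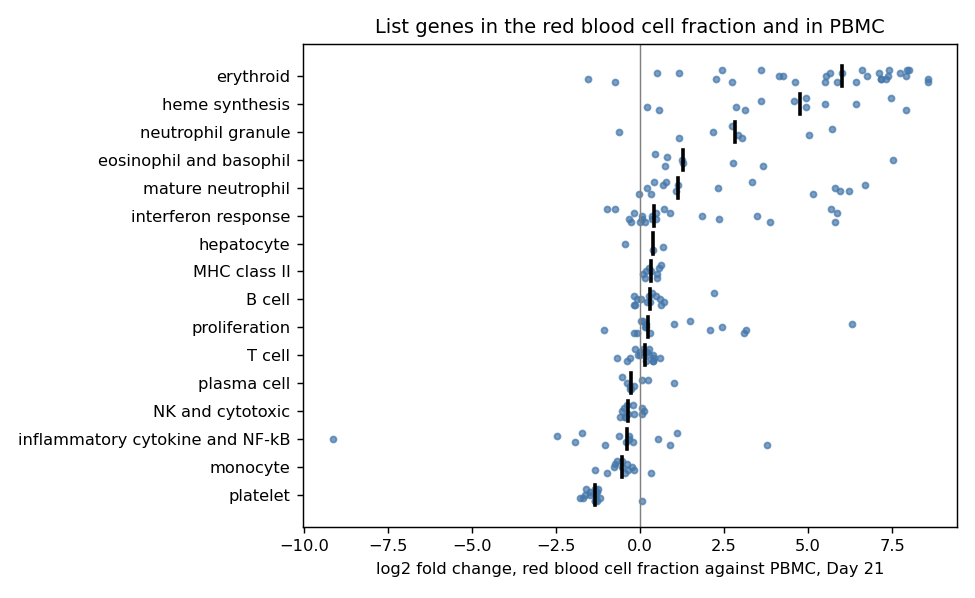
Log2 fold change of each list gene between the red blood cell fraction and PBMC on Day 21 (6 libraries each); points are genes, bars are list medians. Erythroid genes have a median of 6.01 and platelet genes of -1.34.

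CCl4 was compared with saline in the dose set before and after a possible dose on Day 3. On Day 4, neutrophil, platelet, interferon and inflammatory genes were higher in the 12 CCl4 rats than in the 3 saline rats. Of 15 mature neutrophil genes 14 rose, with a median of 1.89. Csf3r stood at 133 ± 53.2 against 22.7 ± 10.1 CPM (2.48, SE 0.31), S100a9 at 455 ± 234 against 79.5 ± 21.9 CPM (2.38, SE 0.36), and Il1r2, a decoy receptor for interleukin 1, was higher by 3.67 (SE 0.48). Of 10 granule genes 5 rose (6 up and 1 down over the list alone). The adjusted p with an estimated correlation was 0.173 and 0.445. Of 14 inflammatory genes 9 rose (adjusted p = 0.173 with an estimated correlation), Il1b, the cytokine interleukin 1 beta, at 85.9 against 14.1 CPM (2.55, SE 0.31). Of 17 platelet genes 10 rose (11 over the list alone, adjusted p = 0.173 with an estimated correlation), and Tubb1, the tubulin of platelets, stood at 19.6 ± 5.67 against 5.56 ± 2.58 CPM (1.78, SE 0.27).

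Of 22 interferon genes 12 rose (14 over the list alone, adjusted p = 0.237 with an estimated correlation). Gbp2, a guanylate-binding protein, stood at 49.4 ± 25.3 against 7.12 ± 0.948 CPM (2.70, SE 0.31), and Ifit3 rose by 2.55 (SE 0.32). Of 10 immediate early genes 4 rose, Jun by 2.15, and of 11 integrated stress response genes 3 rose (4 over the list alone), Atf5 by 1.62, both with an adjusted p = 0.237 with an estimated correlation. Of 13 oxidative stress genes 3 rose, among them Nqo1, a quinone reductase, by 1.88 (adjusted p = 0.481 with an estimated correlation). Of 18 T cell genes 5 fell (9 over the list alone, adjusted p = 0.445 with an estimated correlation), Il7r, the interleukin 7 receptor, at -0.74 (SE 0.17), while Cd3e at -0.10 did not pass. Of 10 p53 response genes 2 rose and 1 fell, with Cdkn1a, an inhibitor of the cell cycle, at 3.51 (SE 0.68). Among 31 erythroid genes 2 fell (adjusted p = 0.627 with an estimated correlation), of 14 B cell genes 0 passed, and Hbb at 0.12 did not. Of 10 glucocorticoid genes 2 rose.

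edgeR called 1145 of 11499 genes on Day 4, 897 up and 248 down, and 122, 647, 1222 and 941 genes for 0.5, 1, 1.5 and 2 ml/kg against saline. With the difference already there on Day 2 taken off, 255 genes were called, 244 of them up, and Il7r stood at 0.08. The count was 498 without saline rat 3 and 637 without saline rat 1. On Day 5 the mean of the CCl4 arms gave 400 genes. Of 13 monocyte genes 5 were up (7 over the list alone), among them Ccr2, a chemokine receptor picked after its value was seen, by 1.46 (SE 0.27). Of 16 mature neutrophil genes 3 were up (10 over the list alone). By single dose on Day 5, edgeR called 0 genes at 0.5 ml/kg (1343 at an unadjusted p under 0.05), 29 at 1, 1278 at 1.5 and 212 at 2 ml/kg.

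**Figure D3:**
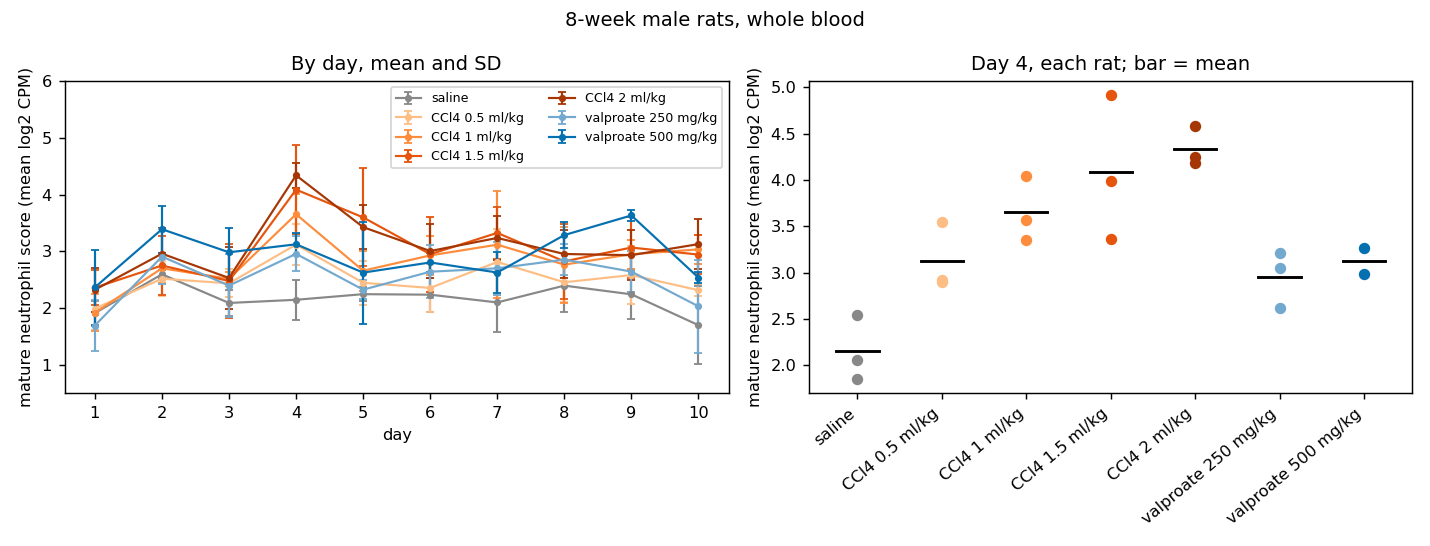
Mature neutrophil score (mean log2 CPM of the list) in saline, CCl4 and valproate arms of the dose set, by day as mean with SD and for each rat on Day 4, with a bar for the mean. On Day 4 the means are 3.12, 3.66, 4.09 and 4.34 for 0.5, 1, 1.5 and 2 ml/kg CCl4, 2.15 for saline, and 2.96 and 3.13 for valproate 250 and 500 mg/kg.

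Within the 12 CCl4 rats of Day 4, genes of neutrophils rose with dose. S100a8, the partner of S100a9, rose by 1.48 per ml/kg on the log2 scale (SE 0.31), reaching 348 ± 22.3 CPM at 2 ml/kg (3 rats), and Serpinb1a, an inhibitor of neutrophil proteases, by 1.92 (SE 0.34). Of 15 mature neutrophil genes 3 passed over all genes and 13 over the list alone, and of 14 inflammatory genes 1 and 8, both with an adjusted p = 0.193 with an estimated correlation. Of 22 interferon genes 0 passed over all genes with edgeR and 10 over the list alone (adjusted p = 0.268 with an estimated correlation). edgeR called 72 of 11147 genes, 68 rising and 4 falling, with 1270 at an unadjusted p under 0.05, and DESeq2 called 298. The count was 0 without rat 3 of 0.5 ml/kg or rat 2 of 2 ml/kg, 1 without rat 2 of 0.5 ml/kg or rat 1 of 1 ml/kg, 9 without rat 1 of 0.5 ml/kg, 40 without rat 3 of 2 ml/kg and 124 without rat 1 of 1.5 ml/kg.

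On the other CCl4 days compared, the mean over the 4 doses gave few genes. On Day 10 the 2 genes called were Oas2, an interferon-induced synthetase, at 1.90 (SE 0.33) and Slfn1, a Schlafen gene, at 1.26, both named after their values were seen. Leaving out 1 rat gave 0 to 11 genes, no gene passed with a block on the replicate number, and another split of the samples called 12. Over the list alone, 12 of 15 mature neutrophil genes and 7 of 9 granule genes were higher on Day 10, with an adjusted p = 0.0668 with an estimated correlation for both lists. Examples are S100a9 at 1.24 (SE 0.30) and Camp, the antimicrobial cathelicidin, at 2.39. On Day 6 edgeR called 0 of 12427 genes, with 1684 at an unadjusted p under 0.05 and 95 by DESeq2. By single dose, 1.5 ml/kg against saline gave 474 genes on Day 6, 203 up and 271 down, and 26 on Day 10, while edgeR called 0 for each of the other 3 doses, with 424 to 1795 at an unadjusted p under 0.05 on Day 6 and 305 to 858 on Day 10. Over the mean of the doses on Day 6, 4 of 9 granule genes and 5 of 11 immediate early genes were higher over the list alone (adjusted p = 0.557 and 0.503 with an estimated correlation), among them Chi3l1, a chitinase-like protein of neutrophils, at 1.01 (SE 0.31). On Day 2, before a dose of either day, edgeR called 0 of 10155 genes, with 186 at an unadjusted p under 0.05 and 0 by DESeq2, and the platelet list, with a median of 0.32 and 0 members over the list alone, had an adjusted p = 0.692 with an estimated correlation. On Day 10, 721 of 10512 genes had an unadjusted p under 0.05, and DESeq2 called 65.

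Isoniazid and valproate, at 4 doses each, were compared on Day 3, their last shared day. Whether this blood was drawn before or after a dose is not given, so the values may be those of rats not yet dosed. For the mean of the CCl4 arms on Day 3 edgeR called 0 of 11340 genes, with 346 at an unadjusted p under 0.05. Averaged over the doses no gene passed over all genes, and members of the monocyte and T cell lists passed over the list alone. In the 12 isoniazid rats, 7 of 13 monocyte genes were higher than in saline over the list alone (median 0.54, adjusted p = 0.344 with an estimated correlation), with Csf1r at 29.2 against 15.4 CPM (0.89, SE 0.19). Of 18 T cell genes, 10 were lower over the list alone (median -0.40, adjusted p = 0.152 with an estimated correlation), Cd3e at -0.48 (SE 0.14). In the 12 valproate rats, 5 of 13 monocyte genes were higher over the list alone (median 0.66, adjusted p = 0.74 with an estimated correlation), with the lectin receptor Clec4a3 at 0.83 (SE 0.22). edgeR called 0 genes for isoniazid, 0 for valproate and 0 between both drugs, with 1181, 1028 and 945 at an unadjusted p under 0.05 and 41, 26 and 9 by DESeq2. These are means over the doses, and of the single doses isoniazid at 1600 mg/kg gave 23 genes against saline, 21 up and 2 down, while edgeR called 0 for each of the others, with 586 to 1363 at an unadjusted p under 0.05. Between both drugs, with no use of the saline rats, 4 of 10 immediate early genes were lower with isoniazid over the list alone (adjusted p = 0.555 with an estimated correlation), Zfp36, which promotes mRNA decay, at -0.39 (SE 0.12).

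On Day 4, valproate at 250 mg/kg (3 rats) and 500 mg/kg (2 rats) was compared with the same 3 saline rats. Of 16 mature neutrophil genes 7 were higher than in saline (12 over the list alone, adjusted p = 0.313 with an estimated correlation), and S100a8 stood at 88.4 ± 25.7 against 29.9 ± 6.25 CPM (1.59, SE 0.21). Of 17 platelet genes 8 were higher (10 over the list alone, adjusted p = 0.0918 with an estimated correlation), Tubb1 by 1.66 (SE 0.27) and Itga2b, a chain of the fibrinogen receptor, by 1.39 (SE 0.23). Of 9 granule genes 3 were higher (4 over the list alone) and of 22 interferon genes 2 (3), both with an adjusted p = 0.529 with an estimated correlation, and of 13 inflammatory genes 2 were higher (6 up and 1 down over the list alone, adjusted p = 0.313 with an estimated correlation). On average the mature neutrophil score did not rise from Day 2 to Day 4, going by -0.172 in these 5 rats and by -0.449 in the saline rats. A gap to saline was there on Day 2, when the same rats had means of 2.91 at 250 mg/kg and 3.63 at 500 mg/kg against 2.60, as they had 2.96 and 3.13 against 2.15 on Day 4. edgeR called 260 of 11227 genes, 193 up and 67 down, with 577 by DESeq2. The count was 23 without saline rat 3, 35 without saline rat 1, 73 without rat 2 of 500 mg/kg and 119 without rat 2 of 250 mg/kg.

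CCl4 and valproate were compared with each other on Day 4 without the saline rats, in a contrast added after the planned ones. Of 15 mature neutrophil genes 8 were higher with CCl4 (13 over the list alone), Il1r2 by 2.33 (SE 0.35) and Csf3r by 1.00 (SE 0.22), and of 22 interferon genes 11 were higher (15 over the list alone), Ifit3 by 1.38 (SE 0.23). Of 31 erythroid genes 5 were lower with CCl4 (10 over the list alone), Sptb, a spectrin of red cells, at -0.97. Of 17 platelet genes 1 was higher, and Tubb1 at 0.11 (SE 0.16) did not pass. edgeR called 572 of 11738 genes, 388 higher and 184 lower with CCl4.

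Age was compared on Day 2 of the age set, before a dose of either day. Rats of 8 to 9 months had more RNA of cytotoxic cells and monocytes and less of immature red cells than rats of 3 to 4 weeks (5 each). Of 12 NK and cytotoxic genes 11 were higher (median 2.03), Ccl5, a chemokine of cytotoxic cells, at 166 ± 10.1 against 31.0 ± 4.67 CPM (2.42, SE 0.19) and Gzmk, a granzyme, by 2.51 (SE 0.21). Of 13 monocyte genes 10 were higher, Cx3cr1, the fractalkine receptor, by 1.64. Of 7 eosinophil and basophil genes 6 were higher and 1 lower, with Hdc, which makes histamine, at 2.95 and Alox15 at -4.59. Of 14 inflammatory genes 6 were higher, Il1b by 1.75, and of 9 plasma cell genes 3 (4 over the list alone), Prdm1 by 1.15. These 5 lists had an adjusted p = 0.182 with an estimated correlation.

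Of 31 erythroid genes 27 were lower at 8 to 9 months (28 over the list alone, median -2.07), Epb42, a protein of the red cell skeleton, at -2.69, and of 12 heme genes 10, with an adjusted p = 0.357 and 0.363 with an estimated correlation. Of 16 proliferation genes 6 were lower (7 down and 1 up over the list alone), Mki67 at -2.74. Of 14 B cell genes 5 were lower, Ebf1, a transcription factor of B cells, at -1.14, and of 21 interferon genes 10 were lower and 3 higher, Isg15 at 6.49 against 94.1 CPM (-3.86, SE 0.51), both with an adjusted p = 0.468 with an estimated correlation. Of 18 T cell genes 5 were higher and 4 lower (5 and 6 over the list alone), Zap70, a kinase of the T cell receptor, at 0.67 and Ccr7, a homing receptor of naive cells, at -0.71. Of 10 glucocorticoid genes 4 were higher and 1 lower, Fkbp5 at 1.00. Hepatocyte RNA, described next, was in these Day 2 libraries. edgeR called 3091 of 11947 genes, 1304 higher and 1787 lower at 8 to 9 months.

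The age set has no saline rats and its day of dosing is not given, so Day 4 was set against Day 2 and Day 9 against Day 7. Between Day 2 and Day 4, transcripts of liver cells were lost from the blood libraries. Of 14 hepatocyte genes tested 11 fell, and the list had an adjusted p = 0.0106 with an estimated correlation. Alb, serum albumin, had 0 counts in all 15 libraries of Day 4, at least 33.1-fold lower than on Day 2 against 3 counts per library, and Serpina1, a protease inhibitor, was at least 13.1-fold lower. With the 11 genes whose Day 4 mean lay under that floor, 6 of them at 0, set to their bound, the median was -1.90. Of 12 NK and cytotoxic genes 4 fell (10 over the list alone, adjusted p = 0.154 with an estimated correlation), Ccl5 at -0.59 (SE 0.10). Of 17 platelet genes 2 fell (5 over the list alone, adjusted p = 0.229 with an estimated correlation). Among 22 interferon genes 4 rose and 3 fell (8 and 4 over the list alone), with Ifit3 at 1.08 and Irf7, a transcription factor of the interferon response, at -1.81 (SE 0.27). Of 13 heat shock genes 0 passed over all genes and 6 were lower over the list alone (adjusted p = 0.199 with an estimated correlation). The ribosomal RNA Rn18s rose by 1.06 (SE 0.20). edgeR called 235 of 12728 genes, 43 up and 192 down, with 1807 at an unadjusted p under 0.05, and DESeq2 called 417, 121 up and 296 down. The count was 711 with a block for the rat, 2342 with Days 1 and 2 as the reference, 2778 for Day 5 against Day 3, a pair chosen after seeing the data, and 145, 147 and 151 without rats 5, 2 and 3 of 8 to 9 months.

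Between Day 7 and Day 9 of the age set many lists moved. Of 16 mature neutrophil genes 14 rose (median 1.13), with Csf3r at 83.8 ± 31.4 CPM on Day 7 (15 rats) and 270 ± 112 on Day 9 (14 rats), a log2 fold change of 1.70 (SE 0.18). Of 14 inflammatory genes 8 rose and 1 fell, Il1b by 1.63 (SE 0.17) and Socs3, a brake on cytokine signals, by 1.87. Of 12 immediate early genes 7 rose, Zfp36 by 0.97. Of 13 monocyte genes 9 fell (10 over the list alone), Cybb, a subunit of the phagocyte oxidase, at -0.90 (SE 0.10), and of 16 proliferation genes 9 fell (10). Of 11 eosinophil and basophil genes 4 fell (6), Il5ra, the interleukin 5 receptor, at -1.85, and of 8 sex-linked genes 5 fell (6). The adjusted p with an estimated correlation was 0.223 for each of these 7 lists.

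Other groups were mixed on Day 9. Of 13 oxidative stress genes 7 rose and 2 fell (adjusted p = 0.245 with an estimated correlation), Nqo1 by 1.32. Of 10 p53 response genes 7 rose and 2 fell, with Gdf15, a stress cytokine, at 1.59. Cdkn1a went from 0.619 ± 0.325 to 3.54 ± 6.77 CPM (2.09, SE 0.38), and by 1.59 without rat 3 of 8 weeks, whose neutrophil and NK scores also stood apart on Day 9. Of 10 glucocorticoid genes 4 rose and 1 fell, with Zbtb16 at 2.35, of 12 integrated stress response genes 5 rose, and of 17 fatty acid oxidation genes 4 rose and 2 fell, with Plin2, a coat protein of lipid droplets, at 1.65 and Cpt1a, which brings fatty acids into mitochondria, at 0.67. Of 31 erythroid genes 16 fell and 2 rose (17 and 2 over the list alone), and of 18 T cell genes 6 fell (adjusted p = 0.835 with an estimated correlation). Among 17 platelet genes 4 rose and 5 fell. Slpi, an inhibitor of neutrophil elastase, rose by 2.86 (SE 0.29). Ribosomal RNA moved with these lists, and Rn28s, which selection for polyadenylated RNA should deplete, went from a mean of 538.9 to 2107 CPM (2.14, SE 0.18). edgeR called 5085 of 13332 genes, 2388 up and 2697 down. Other steps of the same length were looked at after seeing the data. They called 5892 genes for Day 3 against Day 1, 5071 for Day 12 against Day 10 and 4378 for Day 11 against Day 9. The last of these shares the Day 9 libraries. Across genes it had a rank correlation of -0.555 with valproate against saline on Day 4 of the dose set. Day 12 against Day 10 had -0.251 and Day 9 against Day 7 had 0.464. These later steps may thus not be separate from the change on Day 9. On Day 10 against Day 7, chosen after seeing the data, 5473 genes passed, but Cybb stood at 0.02 and Cd4 at 0.18.

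**Figure D4:**
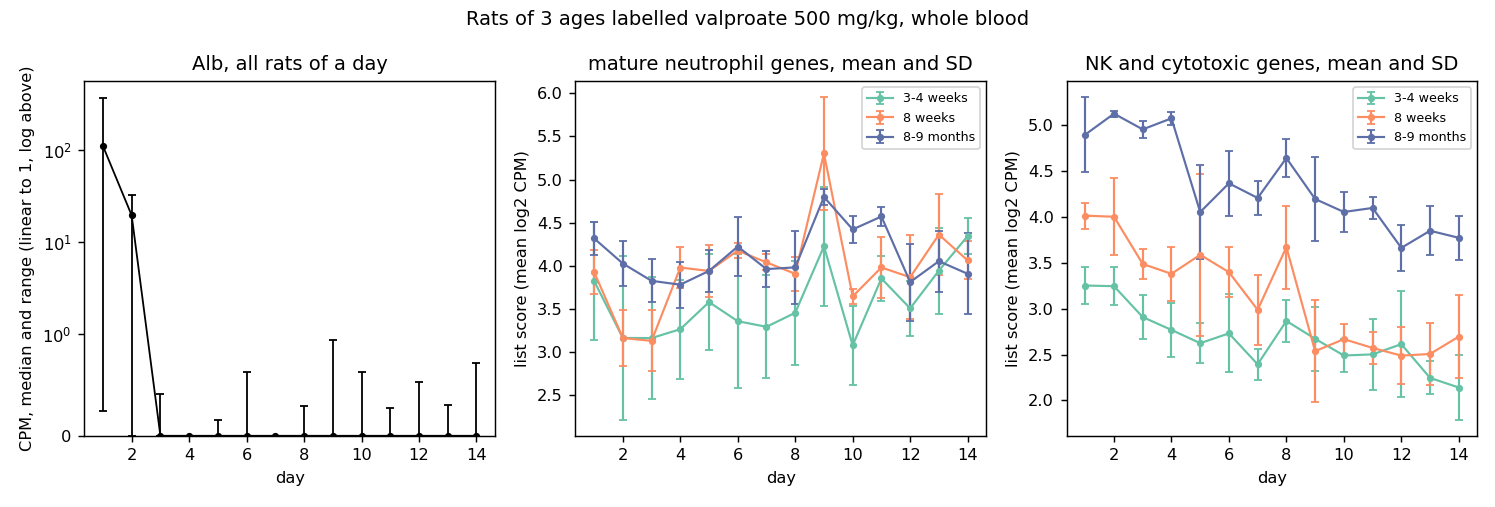
Age set by day, with Alb as median and range of CPM over all rats of a day (linear to 1, log above) and the mature neutrophil and NK list scores (mean log2 CPM) as mean with SD for each age. Alb has a median of 111 CPM per count outside globin on Day 1, 19.5 on Day 2 and 0 on Days 3 to 14.

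The difference between ages in these changes was tested directly. From Day 2 to Day 4, 6 genes changed differently at 8 to 9 months than at 3 to 4 weeks. Isg15 went from 348 ± 282 to 17.6 ± 10.1 CPM per count outside globin in the youngest rats and from 36.7 ± 8.99 to 52.2 ± 32.5 in the oldest (5 each, difference 4.55, SE 0.81), and Oas1a, a sensor of double-stranded RNA, differed by 3.22 (SE 0.58). RT1-T24-3, an MHC class I gene, differed by 2.87 and Spats2l by 6.28, and the linker histone H1f2 by -1.30 and Rnf7 by -1.34. Of 22 interferon genes 2 passed over all genes and 11 over the list alone (median 1.03, adjusted p = 0.546 with an estimated correlation). With a rat block 18 genes passed and with DESeq2 23. The count was 0 without rat 1 or 3 of 3 to 4 weeks or rat 2, 3 or 5 of 8 to 9 months, 1 without rat 4 of 8 to 9 months, 2 without rat 2 of 3 to 4 weeks and 13 without rat 5 of 3 to 4 weeks. From Day 7 to Day 9, 1 gene differed, Atp6v0a1, a subunit of the vacuolar proton pump (1.64, SE 0.26), which went from 210 ± 26.5 to 98.5 ± 17.7 CPM per count outside globin at 3 to 4 weeks and from 104 ± 12.2 (5 rats) to 148 ± 33.5 (4 rats) at 8 to 9 months. With a rat block 11 genes passed and with DESeq2 14. The call of Atp6v0a1 was lost, and the count was 0, without rat 3 of 3 to 4 weeks or rat 2 of 8 to 9 months. The count was 4 without rat 4 of 3 to 4 weeks, and 2 without rat 3, 4 or 5 of 8 weeks or rat 5 of 8 to 9 months.

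In the 6-week set, libraries were compared by title code. Some genes of T cells and platelets were among those with their highest mean in code GD4, in counts summed over dates. By date its T cell genes went both ways, with 8 lower and 1 higher on the fourth date and 13 higher and 0 lower on the sixth. List tests were not run among codes. Cd3d, a chain of the T cell receptor complex, stood at 9.73 ± 1.96 CPM in GD4 and 5.09 to 5.99 in the others (3 sums per code), Rpl18, a ribosomal protein, at 73.3 ± 17.7 against 24.2 to 33.4, and Pf4 at 316 ± 66.8 against 108 to 171. Of 31 erythroid genes 7 differed among codes (15 over the list alone), with Trim58, which acts in enucleation, highest in GD1 at 45.2 ± 15.2 CPM. Of 18 T cell genes 6 differed (11 over the list alone), of 16 mature neutrophil genes 5 (11) and of 12 NK genes 4 (5). Of 17 platelet genes 3 differed (9), of 9 hepatocyte genes 3 (5) and of 22 interferon genes 3 (3). Alb passed 1 CPM per count outside globin in 16 of 24 libraries of the last date and 9 of 24 undated ones. On the earlier dates it reached at most 0.985. The hepatocyte differences may thus rest on those libraries and do not show a liver response of a code. edgeR called 1258 of 14875 genes and DESeq2 3090. Without GD4 rat 3 the count was 266, without GD4 rat 2 it was 293, and grouping by the treatment labels gave 0.

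**Figure D5:**
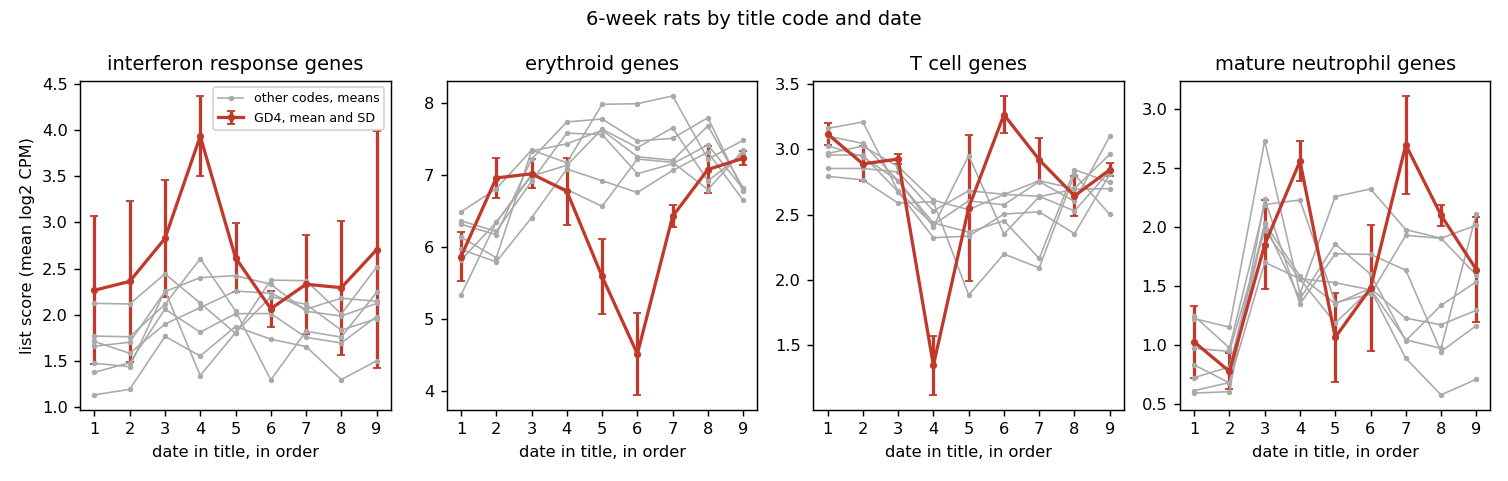
List scores (mean log2 CPM) of the 6-week rats by title date in order, with code GD4 in red as mean with SD of 3 rats and the means of the other 7 codes in grey. The erythroid score of GD4 was 7.02 on the third date, 4.51 on the sixth and 7.23 on the ninth.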

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

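Chosen after the results were seen were all tests of the neutrophil and hepatocyte patterns below and the splits between the sexes. Libraries of the age set on Days 2, 4, 7 and 9 were searched for a sample far from the other rats of its age and day. The measures were total counts, globin share, genes detected and the erythroid, mature neutrophil, interferon response and NK scores. Over 84 tests, each of 1 measure in the rats of 1 age and day, 11 values stood apart, some in the same library. Chance alone gives about 1 in 20 tests, but measures of the same library are not independent of each other.

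The 8-week rat 1 of Day 2 stood apart by its globin share of 51.16% (95% Wilson interval 51.14 to 51.18) and its erythroid score of 4.573. The 3-to-4-week rat 1 of Day 4 had a globin share of 78.42% (95% Wilson interval 78.40 to 78.43). The erythroid score was 5.793 in the 8-week rat 1 of Day 4 and 5.813 in the 8-week rat 5 of Day 9. The 8-week rat 3 of Day 9 had a mature neutrophil score of 6.451 and an NK score of 1.558. The 8-to-9-month rat 4 of Day 7, which has no library from Day 9 on, had a neutrophil score of 3.594 and an NK score of 4.532. The 8-week rat 5 of Day 7 had 32.21 M (mega counts) in all, and the 3-to-4-week rat 3 of Day 9 had 13085 genes detected.

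Changes that differed between groups were found in 3 tests of the difference itself. From Day 2 to Day 4, 6 genes changed differently at 8 to 9 months than at 3 to 4 weeks, namely the interferon-induced Isg15 (difference of log2 fold changes 4.548) and Oas1a (3.219), RT1-T24-3 (2.869), Spats2l (6.281), H1f2 (-1.296) and Rnf7 (-1.34). From Day 7 to Day 9, 1 gene did, Atp6v0a1 (1.64). Between CCl4 and saline rats, 255 genes changed differently from Day 2 to Day 4.

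Signals also stood in libraries that the comparisons did not use. Alb had a median of 111 and a highest value of 370 CPM per count outside globin on Day 1 of the age set, and reached 36.5 CPM on the last date of the 6-week set. On Day 1 of the dose set, before a dose of either day, 2940 genes differed between the isoniazid and saline arms and 2129 between the valproate and saline arms, and the test of both drugs together called 3100 of 13669 genes, Isg15 at -1.74 and Irf7 at -1.38. By dose of valproate, edgeR called 1471 genes at 250 mg/kg on that day, 341 at 1000 mg/kg and 2501 at 2000 mg/kg. At 500 mg/kg it called 0, with 1977 at an unadjusted p under 0.05, so the gap to saline did not follow the dose. For the mean of the CCl4 arms on Day 1 edgeR called 0, with 403 at an unadjusted p under 0.05, and on Day 2 it called 0 for isoniazid and for valproate, with 376 and 565. The libraries titled GC4 had mature neutrophil scores above those of the saline rats of the same day on Day 4 (3.038), Day 6 (2.874), Day 9 (3.692) and Day 10 (2.866). Their scores on Day 5 (1.337), Day 7 (1.102) and Day 8 (2.393) were not above all saline rats of the day.

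The first pattern weighed is the neutrophil RNA of CCl4 rats on Day 4. The mature neutrophil score rose from Day 2 to Day 4 by 1.067 on average (SE 0.158), in 12 of 12 CCl4 rats, while it went by -0.449 in the saline rats and by -0.172 on average and 0.624 at most in the valproate rats, which argues against a shift of the day or of the saline rats as the whole cause. CCl4 and saline libraries had the same places in the order of library numbers on Days 1 to 3, where the score differed by 0.399 at most, against 1.652 on Day 4, which argues against that order. The score rose by 0.818 per ml/kg among the 12 CCl4 rats (two-sided permutation p = 0.00538), which restates the dose trend of these genes in the same libraries and is no separate evidence, so a CCl4 dose given on Day 3 stays a hypothesis. Whether neutrophils entered the blood or other cells left it stays open, since RNA was counted and not cells.

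The second is the liver RNA in the age set on Days 1 and 2. Alb stayed at or below 0.939 CPM per count outside globin on Days 3 to 14, in the days after a dose on Day 3 or Day 8, which argues against hepatocyte RNA released after valproate. The lowest ratio of Apoa1 to Alb on Day 2 was 0.0982 and the highest on Day 1 was 0.0481, so each day had its own proportion of liver transcripts, which is consistent with liver RNA carried over from other libraries. By rat, 3 were under 1 CPM of Alb on Day 1 only, at 0.246 to 0.351, 2 on Day 2 only, both at 0, and 0 on both days. The list's genes are made in hepatocytes, but Tf and Hp are also expressed in blood, with medians of 375 and 25.5 CPM on Days 3 to 14, and no liver sample was used here.

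The other splits of the samples tested whether an arbitrary division calls as many genes, with up to 100 splits per comparison. The real count exceeded the highest of the other splits for Day 9 against Day 2 (1369 against 2), Day 21 against Day 10 (2662 against 56) and the fractions (3572 against 1). The same held for CCl4 on Day 4 (1145 against 3), the dose trend (72 against 1), valproate on Day 4 (260 against 163) and age on Day 2 (3091 against 1401). It also held for Day 4 against Day 2 (235 against 2) and Day 9 against Day 7 (5085 against 1226) of the age set. So it did for its 2 differences between ages (6 against 0 and 1 against 0) and the title codes (1258 against 47). With 40 to 100 splits per comparison, the real one included and no adjustment over the 19 comparisons, such a rank does not exclude chance. Without 1 rat, both differences between ages fell to 0 genes and valproate on Day 4 to 23. Among splits that part as many rat pairs, the highest counts were 2, 0, 1, 0 and 660 for the 5 comparisons within rats, in the order given. For CCl4 on Day 10 the highest other split called more genes than the real one (2 against 12). For CCl4 on Days 2 and 6 and isoniazid, valproate and both drugs on Day 3, with no gene called, the splits can decide nothing, since every split calls as many, and the highest others were 101, 294, 3, 8 and 14 genes. Splits with 101, 294 and 12 genes may point to a structure of the samples other than the arms, which was not tested. For the sexes the splits are too few for such a share, with 10 genes and 1 in the highest other.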

How the results depend on the processing

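The pairs of days named here, the removal of hepatocyte genes and the 6-week set without its last date and undated libraries were chosen after seeing the data. Of 399 counts of genes or lists under an alternative, 297 were within 1.5 times the reported count, 48 were higher and 54 lower. Of 10141 values of the 514 named genes, 9047 kept their direction and side of the threshold, 1056 lost the call and 38 reversed. Other size factors within edgeR and the removal of globin, erythroid or hepatocyte genes left each count within that factor, and so did the 6-week set without its last date (1525). Depth limits, through the filter on low counts, which of 24897 genes are tested, from 10155 for CCl4 on Day 2 to 16378 where counts were summed per rat. On simulated data a 2-fold change was recovered in 46% of genes for Day 9 against Day 2, 13% for CCl4 on Day 2, 29% on Day 4 and 72% for Day 9 against Day 7 of the age set, and whether depth or the spread between rats sets this was not tested. The cause was not tested for the counts and values that follow, except where fewer samples show it.

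DESeq2 gave 259 genes for sex, 95 for CCl4 on Day 6, 65 on Day 10, 298 for the trend, 41 for isoniazid, 26 for valproate, 9 for both drugs, 577 for valproate on Day 4, 417 for Day 4 against Day 2 of the age set, 23 and 14 for the differences between ages and 3090 for the codes. Without a filter on low counts there were 13 for CCl4 on Day 2, 145 on Day 6, 101 on Day 10, 176 for the trend, 106 for isoniazid, 89 for valproate, 75 for both drugs and 694 for valproate on Day 4. With estimated correlations 1 of 128 list calls held.

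With a block for the rat there were 2265 genes for Day 9 against Day 2, 711 for Day 4 against Day 2 of the age set, and 18 and 11 for the differences between ages. A block on the replicate number, which does not mark the same animal elsewhere, gave 460 for valproate on Day 4 and 0 for CCl4 on Day 10.

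With the difference of Day 2 taken off, CCl4 gave 255 genes on Day 4, 4 on Day 6 and 4 on Day 10, and Elane (-0.14), Il7r (0.079) and Rpl30 (0.12) reversed. Other days gave 24 genes (Day 9 against 4, with Hsph1 reversed at 0.068), 3999 (Day 21 against 11), 2342 (Days 1 and 2 as the reference for Day 4), 2778 (Day 5 against 3, with Rn18s at -0.37) and 3021 (Day 9 against 6). With Days 1 and 2 as the reference for Day 9, Kdm6a stood at 0.002. On Day 21 against 11 the reversed genes were Epb42 (0.47), Bcl2l1 (0.18), Abcb10 (0.11), Fech (0.28), Alas2 (0.64), Urod (0.74), Ccr2 (-0.31), Tk1 (0.77), Birc5 (0.22), Asns (0.61) and Slc3a2 (0.41). On Day 10 against 7 they were Tal1 (0.10), Cybb (0.024), Clec4a3 (0.11), Cd4 (0.18), Cd8b (0.41), Hdc (1.18), Mcpt8 (0.93), Ifit3 (-0.75), Oasl (-0.19), Bst2 (0.19), Nlrp3 (-0.007), Dusp1 (-0.064), Sgk1 (-0.27), Slc7a11 (-1.16), Prdx1 (0.13), Sesn1 (0.11), Mcm5 (0.033), Hsph1 (0.10), Atf4 (-0.094), Eif2s3 (0.067) and Mal (0.28).

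The title codes gave 0 genes by treatment label and, in the order of dates, 0, 163, 147, 1268, 2073, 2296, 48, 102 and 451 genes on single dates, which hold fewer counts each.

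Leaving out each rat in turn gave 214 to 2182 genes for Day 9 against Day 2 (2182, 890 and 608 without males 1, 2 and 3, 222 and 214 without females 1 and 3), 1737 (male 3) to 2614 for Day 21 against Day 10, 7 to 14 for sex, 2863 to 3325 for the fractions, 0 to 1 (saline 2) for CCl4 on Day 2, 498 (saline 3) and 637 (saline 1) to 1365 on Day 4 and 0 to 2 (saline 2) on Day 6. On CCl4 Day 10 it gave 11 without saline 2, 5 and 1 without rats 2 and 1 of 2 ml/kg, 4 without rat 2 of 1 ml/kg, 3 without rat 1 of 1 ml/kg and 0 without each of the others. The trend gave 0 (rat 3 of 0.5 and rat 2 of 2 ml/kg), 1 (rat 2 of 0.5 and rat 1 of 1), 9 (rat 1 of 0.5), 40 (rat 3 of 2) and up to 124 (rat 1 of 1.5). Isoniazid gave 0 to 9 (rat 1 of 800 mg/kg), valproate 0 to 6 (rat 2 of 500), both drugs 0 to 1 (rat 1 of isoniazid 400) and valproate on Day 4 23 (saline 3), 35 (saline 1), 73 (rat 2 of 500) and 119 (rat 2 of 250) to 232. Age on Day 2 gave 2368 to 3654, Day 4 against Day 2 of the age set 145, 147 and 151 (rats 5, 2 and 3 of 8 to 9 months) to 230 and Day 9 against Day 7 4449 to 5045. The first difference between ages gave 0 (rats 1 and 3 of 3 to 4 weeks, rats 2, 3 and 5 of 8 to 9 months), 1 (rat 4 of 8 to 9 months), 2 (rat 2 of 3 to 4 weeks) and 13 (rat 5 of 3 to 4 weeks). The second gave 0 (rat 3 of 3 to 4 weeks, rat 2 of 8 to 9 months), 2 (rats 3, 4 and 5 of 8 weeks, rat 5 of 8 to 9 months) and 4 (rat 4 of 3 to 4 weeks). The codes gave 266 and 293 (GD4 rats 3 and 2) to 1302. Where an arm kept 1 rat, it was assumed to vary like the other groups.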

Other observations

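The contrasts of code GD4 by date and the tests of liver RNA in the dose set were chosen after the results were seen, and so were the tests of the erythroid steps, except that of the red-cell share of the tube over all called genes of each step. In the 6-week set, the 3 rats of code GD4 ran through a sequence of changes that set them apart from the other 7 codes, with 0, 585, 0, 2430, 3186, 3936, 576, 0 and 8 genes on the 9 dates. On the second date 11 of 31 erythroid genes, 3 of 12 heme genes and 14 of 17 platelet genes were higher and no gene of these lists lower. On the fourth date interferon genes were higher, 16 of 22, with Mx2, an antiviral GTPase, at a log2 fold change of 4.34 (SE 0.29) and Isg15 at 3.87 (SE 0.31). On the same date 9 of 14 mature neutrophil genes were higher, S100a8 by 2.57 (SE 0.24), and 5 of 11 monocyte genes were lower, Csf1r at -2.49. Among T cell genes 8 were lower and 1 higher, with the costimulatory receptor Cd28 at -2.84. Of 10 neutrophil granule genes 3 were higher and 3 lower, and of 31 erythroid genes 3 were higher and 9 lower. On the fifth date 26 of 31 erythroid, 4 of 9 granule and 2 of 14 mature neutrophil genes were lower and 0 of these lists higher, while 7 T cell genes were higher and 3 lower. On the sixth date 29 of 31 erythroid genes were lower, with Slc4a1 at -3.54 (SE 0.44) and Gata1 at -3.10, while 13 of 18 T cell genes were higher, Cd3d by 2.09, and 8 of 12 NK genes, Nkg7, a protein of cytotoxic granules, by 2.53. On the seventh date 9 of 9 neutrophil granule genes were higher, the precursor stage genes Ngp and Camp by 3.05 and 2.38, and 8 of 17 platelet genes. No drug is named for this code here.

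Other codes had single dates with many genes, GB8 with 624 on the third, GD1 with 515 and 852 on the fifth and sixth, GD3 with 209 on the sixth and GB6 with 130 on the eighth. GD1 had 22 of 31 erythroid genes higher on the sixth date, and GB8 had 17 erythroid genes lower and 7 monocyte genes higher on the third. In the dose set, Alb was counted in 6 of 12 CCl4 libraries of Day 4, up to 3.75 CPM per count outside globin, and in 0 of 8 saline and valproate libraries (two-sided Fisher exact p = 0.0419). It was counted in 2 of 36 CCl4 libraries of Days 1 to 3 and 5 of 12 of Day 5. Single libraries of other arms had it too, 1 of 12 valproate libraries on Day 2 (2.62 CPM) and on Day 3 (3.73 CPM), close to the highest CCl4 value, and 1 of 12 isoniazid libraries on each of Days 1 to 3 (up to 1.48 CPM).

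The third pattern weighed is the erythroid steps of the untreated rats to Days 4, 11, 16 and 18, which lie within a run of library numbers, since runs change between Days 1 and 2 and between Days 9 and 10. These steps cross no such change, which by itself argues against it as their cause. Day 10 against Day 9, which crosses one, called 1 gene, but this count has no bearing on the steps within a run. Day 2 against Day 1 called 2999 genes, and a change of run stays open for that step. The mean erythroid score fell by 1.764 from Day 4 to its lowest, on Day 16, so the score itself was not kept up through daily bleeding. This restates the steps to Days 11 and 16, seen before the test was chosen, and is no separate evidence on red-cell formation. A moving share of red-cell RNA in the tube was looked for through the difference between the red blood cell fraction and PBMC. With erythroid and heme genes left out, at least 86.1% of called genes followed that difference on Days 4, 11 and 18. On Day 16 54% did (54.7% of all called genes). The fraction also held neutrophil RNA, with S100a9 higher by 5.94, and edgeR called 2 genes between it and whole blood. Its difference from PBMC is thus not that of red cells alone, and these percentages cannot decide on a red-cell share at any of these steps. What differed in the sampling of those days stays open, and no biological explanation beyond red-cell formation was tested.

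A dose on Day 8 in the age set may account for the change from Day 7 to Day 9. The log2 fold changes of that step had a rank correlation across genes of 0.464 with those of valproate against saline on Day 4 of the dose set. Day 13 against Day 11 of the age set had 0.478. Day 11 itself differed from Day 7 in 2267 genes, and Day 11 against Day 9 had a rank correlation of -0.555. Day 13 against Day 11 may thus not be separate from the change on Day 9. The step from Day 7 to Day 9 had 0.525 with CCl4 against saline on Day 4, which shares the saline rats, so the resemblance cannot be put down to valproate alone. Genes are not independent replicates. Of 13 rats with the steps to Day 9 and to Day 13, 10 had the higher correlation on Day 9. The mean difference was 0.104 (SE 0.055) and the largest, 0.51, was in a single 3-to-4-week rat. The other 3 were all among the 4 rats of 8 weeks, the age of the dose set, so these data cannot tell.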
